A study of Pseudoramibacter alactolyticus
Neocallimastix lanati (nom. inval.) and Megasphaera elsdenii
Neocallimastix lanati (nom. inval.) and Pseudoramibacter alactolyticus with 23 samples.

How the data were processed

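RNA-seq libraries were made from P. alactolyticus and M. elsdenii in lactate-added monoculture, in coculture with the anaerobic fungus N. lanati, and in that coculture with formate added. RNA was extracted with a silica-column kit (RNeasy), per the labels' protocols, and libraries were made by EMBR-seq, a method that enriches bacterial mRNA by blocking ribosomal RNA during library preparation. The deposited values are raw read counts per protein-coding gene, in 1 table for each species with 1 column per library, and were not normalized. The aligner, the counting program, the genome build, the annotation and any filter are not given in the sources used here, and neither is how reads of the fungus were separated from reads of the bacterium. Whether counting used strand, and how reads shared by near-identical genes were assigned, is not given in the sources used here either, so values of overlapping or duplicated genes are uncertain.

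Libraries were assigned to groups and replicate numbers from their titles. The number of columns without a sample was 0. No pair of replicates agreed within sampling noise, since the chi-square per degree of freedom over genes was at least 17.1 for every pair, and all 23 libraries were used as separate samples. Total counts ranged from 1011252 to 4008895. The spread between libraries beyond counting error, as a common biological coefficient of variation in edgeR, was 0.426 in each species.

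The deposited counts of each species were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 2327 genes in P. alactolyticus and 2072 in M. elsdenii. Library sizes were scaled by TMM factors, which ranged from 0.516 to 1.41 in P. alactolyticus. In M. elsdenii the factors averaged 0.730 ± 0.119 in monoculture (SD, n = 3), 1.07 ± 0.0660 in coculture and 1.20 ± 0.134 with formate (n = 4 each). The 3 groups of a species entered 1 robust quasi-likelihood fit, so that they shared an estimate of the spread, and each comparison was a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of its F. CPM values are TMM-scaled, and shares of counts are percents of the library total. Correlations between libraries were Spearman correlations of log2 CPM with a prior count of 2. The separation of groups was the mean within-group correlation minus the mean between-group correlation, with an exact test over all splits of the libraries.

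The design, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. The rule for named genes asked for genes with a named product. The files do not pair the identifiers with names, so by the same rule at most 2 identifiers that rose and 2 that fell in coculture are given for each species, those with the largest change among genes that passed the threshold, had at least 10 CPM on average in the higher group and had no overlap between the libraries of the groups. P. alactolyticus had 1 such rise. The 23 lists of genes that had been fixed, among them chain elongation, lactate oxidation, formate metabolism and sugar uptake, need gene names and were not analysed here. A reference annotation was not used here.

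On simulated data with the real means, library sizes and spread and 200 changed genes, in 3 draws, the coculture against monoculture test over 2327 genes of P. alactolyticus recovered 21.7% of 2-fold and 82.2% of 4-fold changes, with 2.83% false among its calls. Over 2072 genes of M. elsdenii it recovered 15.1% of 2-fold and 76.0% of 4-fold changes, with 3.87% false. Calls of the wrong sign were 0 in both. The simulated genes varied independently around 1 mean over all libraries, whereas genes of the real libraries deviated together. These rates therefore need not hold for the real data, least of all in P. alactolyticus, whose groups were split within themselves. A test of neighbouring identifiers was also tested on simulated data, where changes placed at random gave a correlation of −0.0356 and changes placed in blocks of 4 gave 0.563 over the 2072 genes of M. elsdenii. Genes varied independently here too, so this does not show that the test tells a response from variation that neighbours share. Alternatives were other scaling factors, removal of the 20 most abundant genes, DESeq2 1.42.0, other filters, only the 2 groups compared, thinned counts, a replicate block, a test against a fold of 1.5, and each library left out in turn. Chosen after seeing the libraries were limma 3.58.1 with voom and quality weights, the share of the 10 most abundant genes as a covariate, the removal of the 3 P. alactolyticus libraries with over 38% of their counts in 10 genes, and leaving out libraries of the group not compared.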

Results

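RNA was sequenced from 2 chain-elongating bacteria, which lengthen short fatty acids to butyrate and hexanoate. Pseudoramibacter alactolyticus and Megasphaera elsdenii were each grown alone with lactate added, together with the anaerobic fungus Neocallimastix lanati, and together with the fungus with formate added. Anaerobic fungi of this kind live in herbivore guts and break down plant cell walls. Each group had 4 libraries, except the M. elsdenii monoculture, which had 3, for 23 libraries in all. Total counts on protein-coding genes ranged from 1173916 to 4008895 per library in P. alactolyticus and from 1011252 to 2008743 in M. elsdenii. Of the 2515 P. alactolyticus genes and 2274 M. elsdenii genes listed, 29 and 31 had no count in any library of that species. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Lactate was added only in the monocultures and the fungus was present only in the cocultures, so a difference between these groups belongs to both changes at once.

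The files pair no gene names with the numeric identifiers, so genes are described by how many changed, by how much, and by their share of the transcripts, with a few identifiers as examples.

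The first question was how the transcripts of M. elsdenii differed between growth with the fungus and growth alone with lactate added. In M. elsdenii 1109 of 2072 tested genes (53.5%) differed in coculture, 584 higher and 525 lower than in monoculture (edgeR, n = 3 and 4). The 584 genes that were higher took 8.60% ± 0.715 of all counts in monoculture and 37.7% ± 3.75 in coculture (SD, n = 3 and 4). The 525 genes that were lower took 54.9% ± 6.12 of the counts in monoculture and 17.5% ± 1.28 in coculture. These sets were chosen on the same libraries, so the shares describe the size of the change and do not test it.

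Many of the changes in M. elsdenii were large. At least a 2-fold difference was estimated for 452 of the higher and 458 of the lower genes, at least 4-fold for 170 and 231, and at least 16-fold for 19 and 16. Gene 2843669115 rose from 2.41 ± 1.36 CPM (TMM-scaled counts per 1e6 counts; SD, n = 3) in monoculture to 91.5 ± 6.0 (n = 4) in coculture, a log2 fold change of 5.22 ± 0.375 (SE, edgeR adjusted p = 2.7e-06). Gene 2843667332 rose from 1.58 ± 1.82 CPM, on 0 to 5 counts per monoculture library, to 187 ± 23.4 CPM, with a log2 fold change of 6.71 ± 0.66 (SE, edgeR adjusted p = 1.81e-05), which was 8.32 without monoculture replicate 2. Gene 2843667104 fell from 468 ± 108 to 19.8 ± 17.0 CPM, with a log2 fold change of −4.56 ± 0.766 (SE, edgeR adjusted p = 0.000616), which was −5.31 without coculture replicate 3. Gene 2843667437 fell by 4.80 ± 1.43 (SE) on the log2 scale (edgeR adjusted p = 0.0164), but its monoculture libraries spread from 10.5 to 280 CPM, and without monoculture replicate 2 its adjusted p in edgeR was 0.162 at a log2 fold change of −2.18. Without coculture replicate 3 that log2 fold change was −6.02.

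**Figure D1:**
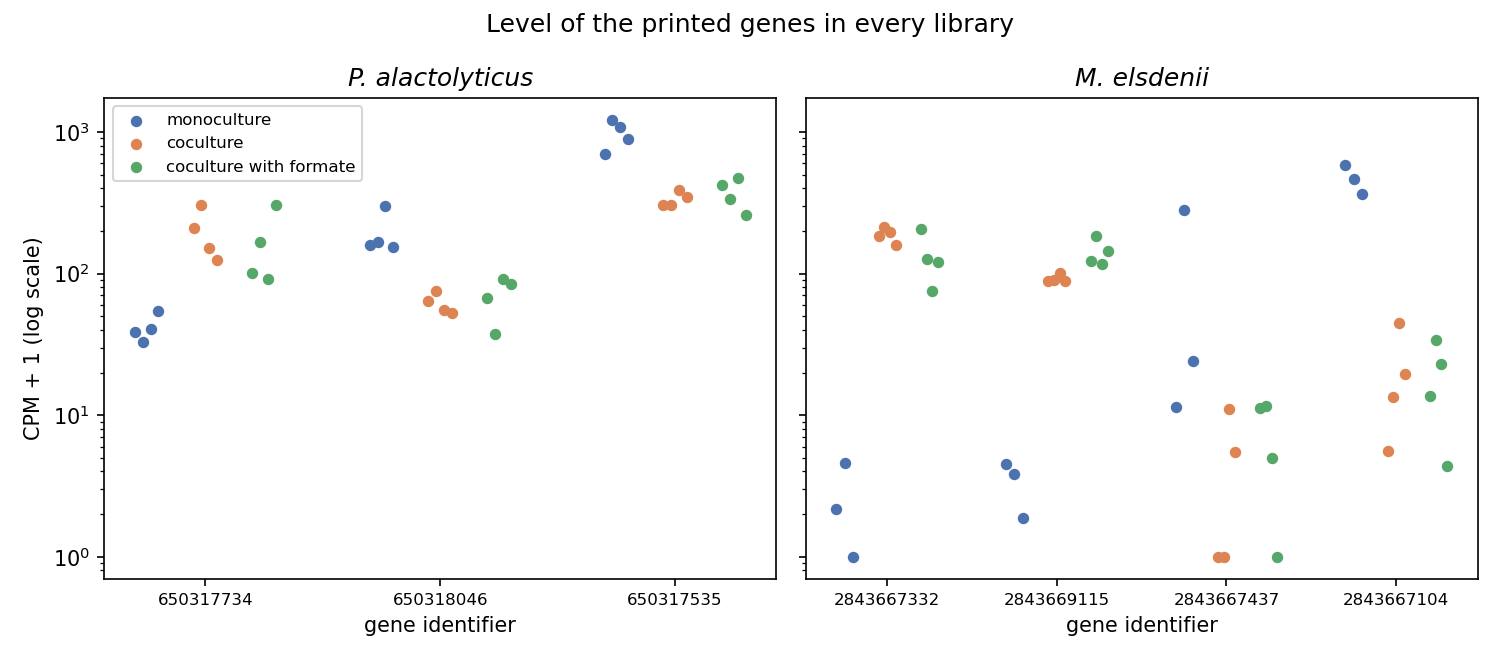
Level of each identifier given in the text in every library, as CPM + 1 on a log axis; each point is 1 library and colours mark the groups. The M. elsdenii gene 2843669115 lies between 88.1 and 100.5 CPM in the coculture libraries and at most at 3.50 CPM in the monocultures.

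Abundant genes were called more often than rare ones in M. elsdenii. With the tested genes ranked by abundance and cut into 3 classes of equal size, 68.7% of the most abundant, 51.3% of the middle and 40.5% of the least abundant class differed between coculture and monoculture. The median SE of the log2 fold change was 0.470 in the least and 0.273 in the most abundant class. The leading transcripts changed as well, since 24 of the 50 most abundant genes in monoculture were also among the 50 most abundant in coculture. The gene with the highest mean abundance held 15.9% ± 2.14 of the counts in monoculture (SD, n = 3) and 19.2% ± 4.02 in coculture (n = 4). Spearman correlations across genes, which are not independent replicates, lay between 0.456 and 0.804 for pairs of 1 monoculture and 1 coculture library. The separation of the 2 groups by these correlations was the largest of all 35 splits of the 7 libraries (exact permutation test, one-sided, p = 0.0286, the smallest this design allows). In 992 genes (47.9%) the 2 groups did not overlap, against 5.71% for chance. Monoculture replicate 2 stood apart, with correlations of 0.682 and 0.753 with replicates 1 and 3, which correlated at 0.959. Its correlations with coculture replicates 1 to 4 were 0.456, 0.562, 0.680 and 0.526. The deviation of monoculture replicate 2 from the rest of its group correlated across genes with those of coculture replicate 3 (Spearman 0.588) and formate replicate 2 (0.491) from theirs. With library totals in place of TMM factors 806 genes were called higher and 273 lower, so that 74.7% of the called genes were higher instead of 52.7%, and the median log2 fold change over all tested genes moved from −0.12 to 0.44.

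**Figure D2:**
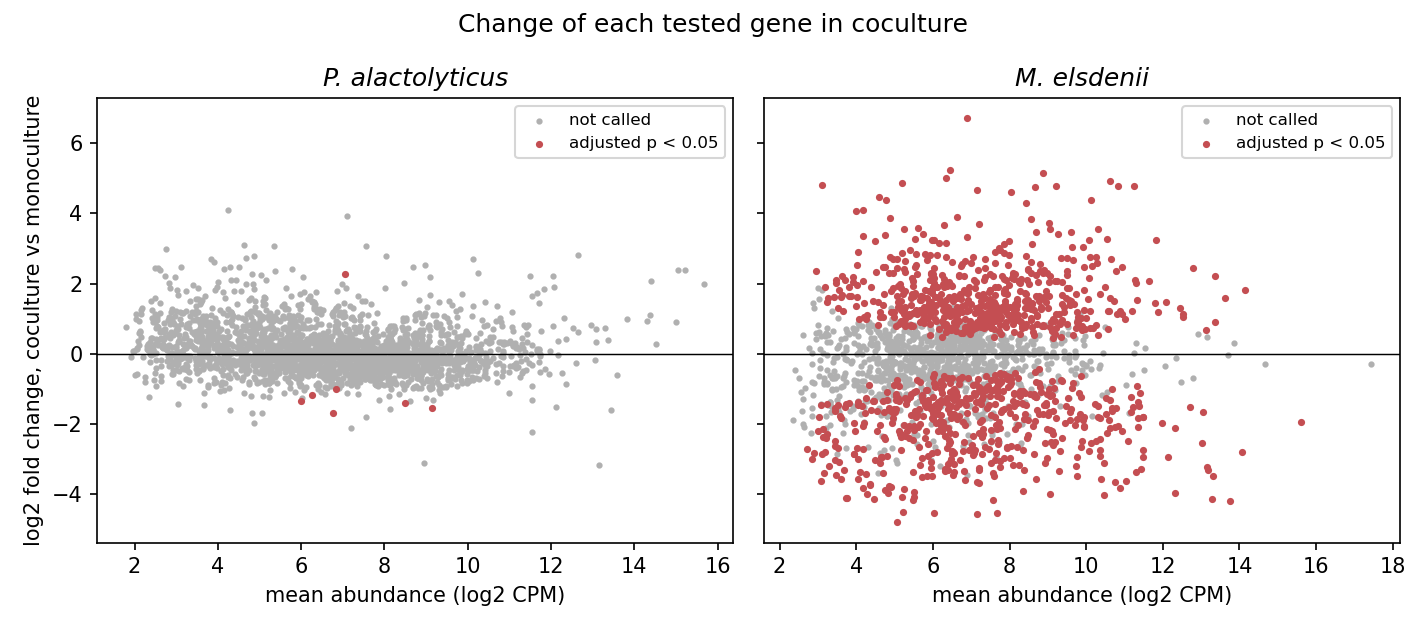
Log2 fold change in coculture against monoculture for each tested gene, against its mean abundance in log2 CPM, with genes at an edgeR adjusted p under 0.05 in red. In M. elsdenii 1109 genes are red on both sides of 0, and in P. alactolyticus 7.

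The same question was asked of P. alactolyticus. Here 7 of 2327 tested genes passed the threshold in coculture against monoculture, 1 higher and 6 lower (edgeR, n = 4 and 4), each by at least 2-fold. Gene 650317734 rose from 40.7 ± 9.24 to 196 ± 79.1 CPM (SD, n = 4 each), a log2 fold change of 2.26 ± 0.413 (SE, edgeR adjusted p = 0.0486). Gene 650318046 fell from 193 ± 70.3 to 60.6 ± 10.4 CPM, a log2 fold change of −1.68 ± 0.314 (SE, edgeR adjusted p = 0.0486). Gene 650317535 fell from 972 ± 224 to 336 ± 40.6 CPM, a log2 fold change of −1.53 ± 0.245 (SE, edgeR adjusted p = 0.0379). Each of these 3 calls ended without any 1 of the 8 libraries compared, at edgeR adjusted p from 0.0585 to 0.196, with the direction kept.

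Beyond these 7, more genes of P. alactolyticus stood apart between the groups than chance gives on average. In 454 of the 2327 genes (19.5%) the coculture and monoculture libraries did not overlap, against 2.86% for chance, and 386 genes had an unadjusted p under 0.05 where 116 would be expected without any difference. Genes deviated together across libraries, so such counts can lie well above their average by chance. The splits were not used to test these 2 counts. The groups were separated more than in any other of the 35 splits of these 8 libraries (exact permutation test, one-sided, p = 0.0286, the smallest this design allows). Correlations between libraries of the 2 groups lay between 0.870 and 0.972, and the 2 groups shared 38 of their 50 most abundant genes. The gene with the highest mean abundance took 1.54% ± 0.489 of the counts in monoculture and 4.88% ± 2.08 in coculture (SD, n = 4 each), and was not among the 7. No test was made of whether the change in P. alactolyticus was smaller than in M. elsdenii, whose genes were not matched to it.

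The count in P. alactolyticus varied widely with the fit and the libraries kept. In 3 libraries few genes held much of the counts. The 10 most abundant genes took 39.8% of the counts in coculture replicate 2 and 43.0% and 38.4% in replicates 2 and 4 of the coculture with formate, against 11.0% to 24.5% in the other 9 libraries. Without these 3 libraries 247 genes were called, 126 higher and 121 lower, and a fit of only the monoculture and coculture libraries called 164, 101 higher and 63 lower. With all libraries, DESeq2 called 121 genes, 75 higher and 46 lower, and limma with quality weights 339, 192 higher and 147 lower. Leaving out any 1 of the 8 compared libraries gave 0 calls in edgeR, with 244 to 360 genes at an unadjusted p under 0.05, where DESeq2 on all libraries called 121. Leaving out replicate 1, 2, 3 or 4 of the coculture with formate, which shares the fit, gave 13, 10, 18 and 29 calls. Called in common were 96 genes, 58 higher and 38 lower, each with the same sign, by the fit without the 3 libraries, the fit of 2 groups, and a fit with the share of the 10 most abundant genes as a covariate, which called 238, 107 higher and 131 lower. These fits used largely the same monoculture and coculture libraries, so their overlap is not independent support.

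**Figure D3:**
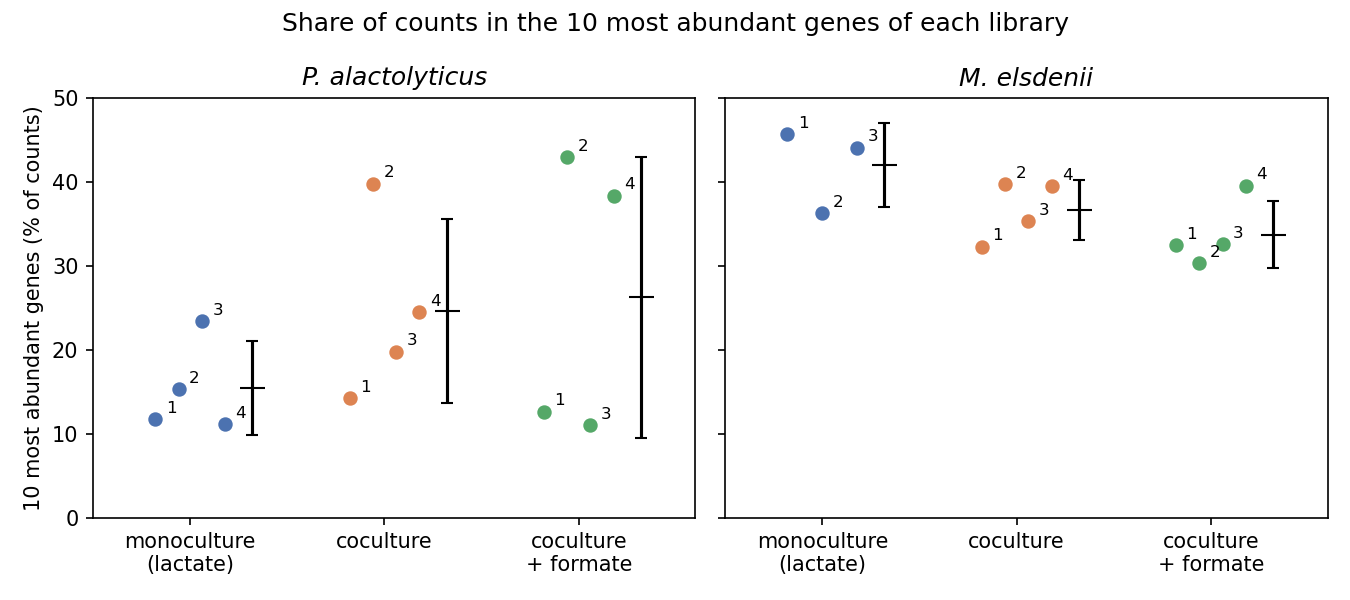
Percent of all counts in the 10 most abundant genes of each library, with points numbered by replicate and bars for the group mean ± SD. In P. alactolyticus coculture replicate 2 and replicates 2 and 4 of the coculture with formate lie between 38.4% and 43.0%, above the other 9 libraries.

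The second question was what adding formate did to the cocultures. No gene passed the threshold in M. elsdenii, where edgeR called 0 of 2072 genes (n = 4 and 4), with 83 at an unadjusted p under 0.05 and a smallest adjusted p of 0.152. DESeq2 called 19 genes, 2 higher and 17 lower, edgeR on the 2 groups alone called 1, and limma called 4. For 1216 genes (58.7%) the 95% confidence interval of the fold change lay within 2-fold in either direction. The 2 groups shared 46 of their 50 most abundant genes, and their separation was not larger than chance (10 of 35 splits as large, exact permutation test, one-sided, p = 0.286). In 109 genes (5.26%) the 2 groups did not overlap, against 2.86% for chance. Genes 2843667332 and 2843669115 stood at 131 ± 54.2 and 141 ± 31.1 CPM with formate (SD, n = 4), at log2 fold changes of −0.52 ± 0.407 and 0.62 ± 0.245 (SE) from the coculture without it.

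In P. alactolyticus adding formate also gave 0 calls among 2327 genes in edgeR (n = 4 and 4), with 23 genes at an unadjusted p under 0.05 where 116 would be expected, and DESeq2 called 0. The formate group was split within itself, since replicates 2 and 4 had the concentrated counts described above and replicates 1 and 3 did not. Correlations between the formate libraries of the 2 kinds went down to 0.823. Without the 3 concentrated libraries edgeR again called 0 genes, now with 670 at an unadjusted p under 0.05, and limma with quality weights, which counts such libraries less, called 165, of which 163 were lower with formate. The 95% confidence interval lay within 2-fold for 1172 genes (50.4%), and 46 of the 50 most abundant genes were shared. The separation of the groups was not larger than chance (24 of 35 splits as large, exact permutation test, one-sided, p = 0.686). In 28 genes (1.20%) the groups did not overlap, against 2.86% for chance.

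The cocultures with formate were also set against the lactate monocultures, which are the same control libraries as above. In M. elsdenii 1067 of 2072 genes (51.5%) differed, 556 higher and 511 lower (edgeR, n = 3 and 4), and library totals in place of TMM factors gave 858 higher and 218 lower genes, 79.7% of them higher instead of 52.1%. The genes that were higher took 7.60% ± 0.733 of the counts in monoculture and 34.7% ± 1.32 in the coculture with formate (SD, n = 3 and 4), and those that were lower took 55.9% ± 6.07 and 20.5% ± 2.41. Gene 2843669115 had a log2 fold change of 5.85 ± 0.380 (SE, edgeR adjusted p = 2.71e-06) and gene 2843667104 one of −4.71 ± 0.769 (SE, edgeR adjusted p = 0.000557). Over the alternatives run these ranged from 5.47 to 6.56 and from −5.53 to −3.91, and both genes stayed called.

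In P. alactolyticus 28 of 2327 genes differed between the coculture with formate and the monoculture, 9 higher and 19 lower (edgeR, n = 4 and 4). Gene 650317535 stood at 371 ± 93.6 CPM with formate (SD, n = 4) against 972 ± 224 in monoculture, a log2 fold change of −1.39 ± 0.244 (SE, edgeR adjusted p = 0.0281). This call ended without monoculture replicate 2, 3 or 4, coculture replicate 1 or 4, or formate replicate 2 or 4, each left out alone, at edgeR adjusted p from 0.0530 to 0.103. The groups did not overlap in 247 genes (10.6%), against 2.86% for chance, while their separation by correlation was not larger than chance (7 of 35 splits as large, exact permutation test, one-sided, p = 0.2). More genes were called higher than lower without the 3 concentrated libraries, at 124 and 88 of 212, and in DESeq2, at 98 and 50 of 148. More were lower with the covariate, at 117 higher and 131 lower of 248, and with quality weights, at 92 higher and 137 lower of 229. A fit of only these 2 groups called 0 in edgeR, with 289 genes at an unadjusted p under 0.05. Among the monocultures, leaving out replicate 1, 2, 3 or 4 gave 3, 1, 5 and 6 calls. Leaving out replicate 1, 2 or 4 of the coculture with formate gave 47, 1 and 4 calls, and leaving out replicate 1, 2, 3 or 4 of the coculture without formate, which shares the fit, gave 3, 12, 9 and 1.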

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

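The tests of M. elsdenii replicate 2 and of abundant genes, and those of the concentrated libraries, were chosen after the results were seen. Among 43 groups of values checked for a library far from the others, 4 held one, and chance gives about 5% of such groups. Groups of fewer than 4 libraries were not checked, which leaves out the M. elsdenii monocultures and so their replicate 2. Gene 650318046 stood at 299 CPM in P. alactolyticus monoculture replicate 3, against 152 to 166 in the other 3. Gene 2843669115 stood at 100.5 CPM in M. elsdenii coculture replicate 3, against 88.1 to 89.2. Replicate 4 of the M. elsdenii coculture with formate had a TMM factor of 1.0, against 1.25 to 1.28, and 2149 genes with a count, against 2206 to 2217.

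In M. elsdenii the coculture differed from the monoculture in 1109 of 2072 genes. Monoculture replicate 2, which stood apart, does not account for this, since without it 1186 genes were called, and with the 20 most abundant genes removed 1120 were called. None of the other 34 splits of the 7 libraries came near the real count, the highest calling 197 genes, so 1 of 35 splits gave as many. This is the smallest share that 35 splits allow, so chance is made unlikely but not excluded. Against the monoculture, the coculture with formate called 1067 genes, with a highest other split of 6 and 1 of 35 splits as large. Both the lactate and the fungus differed between these groups, so the response to either stays open and was not tested.

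In P. alactolyticus 3 libraries had counts concentrated in few genes, and these crossed the groups. The 3 had the lowest totals, 1173916 to 1351777 against at least 1638676 in the other 9. Thinning to 1 total by construction leaves shares as they are (a gap of 13.9 percentage points between the lowest of the 3 and the highest of the 9, before and after). Fewer reads drawn at random therefore do not by themselves raise the share. A process that lowered the totals and also concentrated the counts stays open, since thinning cannot test it. Chance amplification of different molecules in each library is argued against by a Spearman correlation across genes of 0.790 between the deviation of coculture replicate 2 from its group and that of formate replicates 2 and 4 from theirs, which was 0.876 over the 1255 genes with a mean count of at least 200. Reads of the fungus also stay open, because the one fungus-free library that deviated the same way, monoculture replicate 3, is a single library. Its deviation correlated at 0.531 with that of coculture replicate 2 and at 0.652 with that of formate replicates 2 and 4. A shared state of the cultures, such as a different growth phase at harvest, or RNA quality, may lie behind the concentrated counts and was not tested.

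The splits of the P. alactolyticus libraries show the same structure. For coculture with formate against coculture, the real split called 0 genes, a count that all 35 splits reach by construction, so the count of splits decides nothing there. The split that called most, 1041 genes, set coculture replicates 1 and 2 with formate replicates 2 and 4 against the rest. For coculture with formate against monoculture, 3 of 35 splits called at least the real 28 genes, so chance cannot be excluded, and the highest other split called 314 and set monoculture replicates 1 and 3 with formate replicates 2 and 4. For coculture against monoculture, 1 of 35 splits called as many as the real 7, the others at most 0. This is the smallest share that 35 splits allow, so chance is made less likely for that count but not excluded. The 7 calls also ended when any 1 of the libraries compared was left out. In M. elsdenii the coculture with formate against coculture also called 0 genes, and the highest other of the 35 splits called 0, which likewise decides nothing.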

How the results depend on the processing

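The covariate, the quality weights, the removal of the 3 concentrated libraries and of libraries of the group not compared were chosen after seeing the data. In M. elsdenii coculture against monoculture gave 798 to 1233 calls over the alternatives run, and the coculture with formate against monoculture 767 to 1198, within 1.5 times the reported counts. For P. alactolyticus coculture against monoculture (7 calls), DESeq2 size factors in edgeR, upper-quartile factors, removal of the 20 most abundant genes and thinning each gave 2, library totals 1, DESeq2 121, only 2 groups 164, the replicate block and the test against a fold of 1.5 each 0, the covariate 238, quality weights 339 and removal of 3 libraries 247. For the coculture with formate against monoculture (28 calls), the same gave 11, 11, 10 and 23, library totals 0, DESeq2 148, only 2 groups 0, the replicate block and the test against a fold of 1.5 each 1, no filter 13, the covariate 248, quality weights 229 and removal of 3 libraries 212. With each library left out in turn the first count ranged from 0 to 29 and the second from 1 to 47. Beside these counts of 0, edgeR had 326 genes (replicate block, coculture), 165 (fold of 1.5, coculture), 165 (library totals, formate) and 289 (2 groups, formate) at an unadjusted p under 0.05. Formate against coculture gave 165 calls with quality weights in P. alactolyticus, and 19 (DESeq2), 1 (only 2 groups) and 4 (quality weights) in M. elsdenii, beside 0 in edgeR. The fit of 2 groups, and the removal of libraries, changed the spread estimate as well as the libraries, and the cause of the other changes was not tested.

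Same-numbered replicates deviated together in some pairs and apart in others, so the numbers were not read as pairs. Pearson correlations across genes of their deviations from the group means ran from −0.449 to 0.485 for P. alactolyticus coculture against monoculture, from −0.402 to 0.695 for formate against coculture and from −0.649 to −0.0866 for formate against monoculture, and 1, 2 and 0 of 4 correlated best with their own number. In the second of these, replicates 2 and 3 did so, at 0.686 and 0.695. In M. elsdenii they ran from −0.421 to 0.601, from −0.402 to 0.345 and from −0.212 to 0.596, with 1 best with its own number in each. With the block M. elsdenii coculture against monoculture had 901 calls.

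Of 518 values of named genes under alternatives, 415 stayed on their side of the threshold, 97 lost the call and 6 reversed, all between the cocultures, where none was called. These were gene 2843667104, at 0.088 with library totals, 0.35 with quality weights and −0.59 to 0.63 with each library left out, gene 2843667437, at −0.98 with the covariate, and gene 650317734, at 0.0097 without coculture replicate 2 and down to −0.72 with other libraries left out. The other tests foreseen for gene lists were not run, since the lists need names. Depth limits the less abundant genes, whose standard errors were the largest.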

Other observations

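The tests in this part were chosen after the results were seen, as was the width of the stretch of 25 identifiers. Genes of M. elsdenii with successive identifiers were called together in coculture against monoculture more often than in shuffles. Of the 1109 called genes 414 (37.3%) lay in 98 runs of at least 3 successive identifiers called in the same direction, 62 higher and 36 lower, where 1000 shuffles of the calls gave 49.7 runs on average and at most 69. The longest run held 19 genes, all higher, and the longest lower run held 12, against at most 10 in the shuffles. The shuffles took genes as independent, so they do not tell a response to coculture from variation that neighbours share. In the coculture with formate, set against the same monocultures, the longest run also held 19 genes. Whether successive identifiers are adjacent genes is not given in the sources used here.

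In P. alactolyticus 4 of the 6 genes that fell in coculture lay within 19 successive identifiers. Random draws of 6 genes put at most 3 within 25 (permutation test, 10000 draws, one-sided, p = 1e-04, the smallest they can give). The draws took genes as independent, whereas neighbours also varied together between the cocultures with and without formate (Spearman correlation 0.205 between successive identifiers). Genes called by chance could then also cluster, so this p does not exclude chance. The stretch of 25 identifiers was picked for holding the most falling genes, and over its 25 tested genes the median log2 fold change was −0.55, with 17 below 0. Against the same monocultures, the coculture with formate had 7 of its 19 falling genes within 24 successive identifiers, and over the 25 tested genes of the stretch picked in the same way the median was −0.90, with 20 below 0. Mean log2 CPM over the latter stretch was 6.25 ± 0.19 in monoculture, 5.89 ± 0.14 in coculture and 5.29 ± 0.46 with formate (SD, n = 4 each). The formate mean follows the split within that group, since replicates 1 and 3 stood at 4.97 and 4.85 and the concentrated replicates 2 and 4 at 5.82 and 5.53, against 5.72 to 6.02 in the coculture libraries. The calls of the first comparison ended without any 1 of its 8 libraries, where edgeR called 0 genes, with 244 to 360 at an unadjusted p under 0.05, and DESeq2 on all libraries called 121. Those of the second fell from 28 to 1 without monoculture replicate 2, coculture replicate 4 or formate replicate 2, and to 0 in edgeR on only its 2 groups, with 289 at an unadjusted p under 0.05, where DESeq2 called 148.

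The log2 fold changes of M. elsdenii in coculture correlated between successive identifiers at a Spearman correlation of 0.423 across genes, against at most 0.0814 in 1000 shuffles. In P. alactolyticus this was 0.259 against at most 0.0699. Between the cocultures with and without formate, where edgeR called no gene, it was 0.236 in M. elsdenii and 0.205 in P. alactolyticus. Neighbours thus varied together there as well, and in P. alactolyticus nearly as much as in coculture against monoculture. The next 2 points hold only if identifiers follow the order of the genes, which is not given in the sources used here. Reads shared between directly adjacent genes do not account for all of the correlation in M. elsdenii, since genes 2 identifiers apart still correlated at 0.326. A broad trend along the chromosome is argued against, on that condition, by a correlation of 0.00581 between M. elsdenii genes 50 identifiers apart. A candidate explanation is that neighbours belong to shared transcription units, as is common in bacteria. It is a hypothesis from these data and was not itself tested.

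In P. alactolyticus 8 genes were among the 10 most abundant in all 3 concentrated libraries, and 3 of them also in all 4 monocultures.

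The effects of coculture on the concentration of counts were compared between the species. The share of the 10 most abundant genes was 9.17 percentage points higher on average in coculture in P. alactolyticus, but 4.10 without coculture replicate 2. In M. elsdenii it differed by −5.32, by −3.49 without monoculture replicate 1 and by −8.19 without monoculture replicate 2. With all libraries the species differed by 14.5 points (exact permutation test within species, two-sided, p = 0.0424, adjusted p = 0.255 over 6 such comparisons), which does not pass the correction.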
